A study of Homo sapiens with 6 samples.

How the data were processed

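RNA carrying N1-methylguanosine (m1G) was enriched with an anti-m1G antibody from fragmented polyA+ RNA of PANC-1 cells, an established human line of pancreatic ductal adenocarcinoma. Cells had been transfected with control siRNA or with siRNA against TRMT5, the methyltransferase that places m1G next to the anticodon of tRNAs, and the depletion lasted 4 days. Per the labels, each condition had 1 input library and 2 m1G precipitates, which makes 6 libraries, all of the same batch. The labels do not say whether the paired precipitates came from separate cultures.

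The 2 deposited files are peak lists of the whole series, and neither marks a condition, a library or a replicate. Per the submitters' processing notes, the tools included STAR 2.7.1, SAMtools, Picard, bedtools, MACS2 2.2.5, featureCounts and ChIPseeker, and the genome build was GRCh38, and the submitters also name edgeR and DESeq2. Roles, order and settings are not given in the sources used here, and neither is which libraries were pooled for the peak calls. The first list holds 6264 summits of 1 bp from 5921 MACS2 peaks. Its deposited value is the −log10 of a p-value or q-value per summit as MACS2 writes it, and which of these it is was not stated. It ran from 2.01 to 126. The second list, from MeTDiff, holds 18431 peaks on 8386 Ensembl gene IDs, with strand and blocks. Its deposited columns give a p-value per peak, the log10 of its false discovery rate (FDR) and the fold enrichment, a ratio of precipitate over input. These meanings were read from the column order and the values. Of the 4270 IDs with 2 or more peaks, 1837 (43.0%) had a p-value held by 2 or more of them. The highest deposited FDR was 0.0501, which is 0.05 after rounding. Scores and folds were used only to describe, rank or filter peaks within their own list.

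The lists carry no read counts, so the depth of each library is unknown and no value has an error over replicates. A comparison of knockdown with control, the direction of change of gene lists, and TRMT5 levels per library were therefore not analysed here. Shares have 95% Wilson intervals, except the share of genes with a peak at the 3′ end, which has an exact (Clopper-Pearson) interval, and both cover counting error only. Base composition and assignment to UTR, coding sequence or exon need a genome sequence and transcript models, which were not used here.

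Genes were named by position with a RefSeq gene table of the same build (GRCh38.p14), since 0 of the Ensembl IDs matched its Ensembl column. An ID took the name of the only gene whose span overlapped all of its peaks, small RNA genes aside, and each gene kept the ID with most peaks. This named 6419 IDs and 15382 peaks (83.5%, interval 82.9 to 84.0). Of the remaining IDs, 1266 fitted several genes, 172 fitted none and 529 came second to another ID of the gene. A summit took the gene of the only span holding it, which held for 5206 summits, while 648 lay in several spans and 410 in none. A name is thus that of the gene span around the peak, and an antisense or unannotated transcript there would carry it too. Strand was taken from the MeTDiff list.

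Overlap was the share of summits inside the blocks of a MeTDiff peak, set against 1000 placements of each summit at random in the span of its own gene (one-sided permutation test, smallest possible p = 0.001). Where a summit was widened to a window, only 20 placements were drawn. Placement had been planned within exons, and gene spans were used in place of exons because transcript models were not used here. For location, also planned by transcript feature, the midpoint of a peak was placed within 500 bp of the 5′ end or the 3′ end of its gene. Genes with a peak at the 3′ end only were compared with genes with a peak at the 5′ end only (exact binomial test, two-sided). For 24 gene lists, fixed before the data were examined and holding 921 genes of which 919 were in the gene table, the share of genes with a peak was compared with that of all other genes. The test was Fisher's exact test, two-sided, over a background of 20011 protein-coding and listed noncoding genes, with Benjamini-Hochberg adjustment over the lists. Genes are not independent replicates, and these p-values describe the lists, not variation between cultures.

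Genes named in the text were TRMT5 and NES, the 10 genes with the largest fold or score of each peak list, and up to 4 members of each gene list with the smallest p or the highest score. Exceptions are stated. Many genes that this rule names are not reported here, and the choice among them was made after their values were seen. Alternative settings used a larger minimum overlap, the top-ranking peaks, whole spans in place of blocks, another random placement, another background and strata of gene span in place of exonic length. Further alternatives were chosen after seeing the data, and the closing part gives their effect. The tests were checked on simulated data. Random positions in 3000 genes gave an excess of 0.217% over random placement, and 30% planted positions gave 29.2%. Of 4 planted gene lists 4 were called, and of 20 others 0 were. A planted share of 70% at the 3′ end gave 67.9%. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1 were used.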

Results

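To find mRNAs that carry m1G in PANC-1 pancreatic cancer cells with and without TRMT5, m1G-containing RNA fragments were precipitated and sequenced beside their input. The design had 1 input and 2 precipitates from control cells, and 1 input and 2 precipitates from cells depleted of TRMT5 for 4 days. The results below describe 2 peak lists of the whole series, which do not separate the conditions. Every fold enrichment, score and FDR of a peak is the authors' own value, without replicate error. The comparison of TRMT5-depleted with control cells was not analysed here.

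The MeTDiff list placed the strongest enrichment of m1G RNA over input in HDGF, a growth factor gene, at 73.9-fold (chromosome 1, 156751445 to 156751644, FDR 0.00295). TRNP1 followed at 68.0-fold, and then SMAD3, a transcription factor of TGF-beta signalling, at 66.0-fold. MELTF reached 64.5-fold, in a peak that overlapped one of another gene ID, and the triosephosphate isomerase pseudogene TPI1P1 64.2-fold. WSB2, with 61.5-fold, ADCY3, an adenylate cyclase gene, with 60.5-fold, and TOM1, with 59.6-fold, came next, ahead of HELZ2 with 59.5-fold and SAMD1 with 55.5-fold. All 10 genes also held a MACS2 summit, and in 5 of them the peak of largest fold contained a summit. In 4 of the 10 the peak lay within 500 bp of the 5′ end of the gene, as in SMAD3, where its midpoint was 442 bp from that end (chromosome 15, 67065969 to 67066118). In 0 of the 10 it lay within 500 bp of the 3′ end. No read counts were available, so how many input reads each of these ratios rests on is unknown.

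Over the whole MeTDiff list the median fold enrichment was 4.24, from 1.03 to 73.9, and the median peak covered 150 bp of transcript. Of the 18431 peaks, 6094 were spliced over several blocks (33.1%, interval 32.4 to 33.7). Of the 6419 named genes, 2726 had 1 peak and 763 had 5 or more. The folds often lay on coarse steps. Of the 16087 folds under 10, 38.0% (interval 37.2 to 38.7) were multiples of 0.25 within 0.005, where evenly spread values would give 4%.

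In the MACS2 list, PICALM, a clathrin assembly gene, had the highest score in a named gene, 112 (summit at 86068945 on chromosome 11). MOGS, a glucosidase of N-glycan processing, had 111. The actin-severing gelsolin gene GSN had 110, and the riboflavin transporter gene SLC52A2 had 105, beside a MeTDiff peak that overlapped one of another gene ID. Scores from 93.0 to 100 followed for EIF3B, SLC66A2, the pyruvate kinase gene PKM, RNASET2, IGFBP2 and the splicing factor gene SRSF9. All 10 genes also had a MeTDiff peak, with largest folds from 8.97 in PKM to 54.2 in SRSF9. In 9 of the 10 that peak contained a summit. The median score over the list was 16.4. A summit of score 126, above that of PICALM, lay in no gene span, 15 bp from DNAJB11 (chromosome 3, 186570705).

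NES, which encodes the intermediate filament protein nestin and is named with TRMT5 in the title of the study, carried peaks in both lists. It had 5 MeTDiff peaks on its own strand and 6 MACS2 summits (gene span 156668763 to 156677407 on chromosome 1). The fold enrichments were 18.2 for the peak nearest the 5′ end, which joins 3 blocks between 156673484 and 156677258, then 6.82, 4.64, 9.62 and 12.9 towards the 3′ end. FDR values ran from 1.8e-07 to 6.5e-06. Of the 6 summits, 5 lay inside a MeTDiff peak, and the highest, with a score of 30.9, was at 156669502. TRMT5 itself (chromosome 14, 60971441 to 60981690) held 3 MeTDiff peaks with folds of 3.60, 3.25 and 1.75, each with an FDR of 0.00024. Its only summit, at 60981167 with a score of 8.88, was outside those peaks. A further MeTDiff peak in the TRMT5 span, at 60981214 to 60981314 with a fold of 6.25, belonged to another ID on the opposite strand and was not counted for TRMT5. The summit lay nearer to that peak than to any peak of TRMT5. Summits carry no strand, so it may belong to that ID and not to TRMT5. These values are not split by condition, so they give no TRMT5 level in depleted cells.

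**Figure D1:**
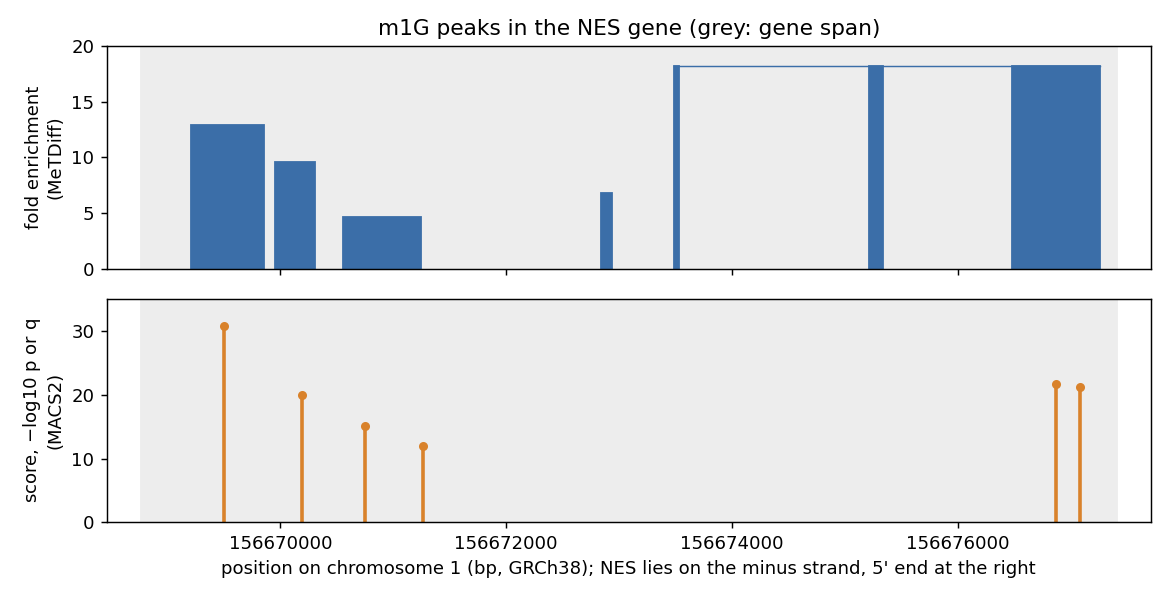
m1G peaks in NES along chromosome 1 (bp, GRCh38). The upper panel gives the fold enrichment of the 5 MeTDiff peaks (bars, with a line joining the blocks of a spliced peak), and the lower panel the score of the 6 MACS2 summits (lines with points). The peak with the largest fold, 18.2, lies at the right, where the 5′ end of the gene is, and the summit of highest score, 30.9, at the left.

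Several groups of genes had a peak more often than other genes in each peak list, tested separately. Among them were genes of the actin cytoskeleton, stress responses, RAS, MAPK and PI3K signalling, splicing, glycolysis, translation factors and cytosolic ribosomal proteins. In the MeTDiff list 15 of the 24 gene lists had a higher share of genes with a peak than all other genes, of which about 31.0% had one, and 5 had a lower share. In the MACS2 list 12 were higher and 1 was lower, against about 15.5% of other genes. A gene must be transcribed to be precipitated, and the files hold no expression values, so a share reflects expression as well as methylation. When only genes with a peak in either list served as background, 3 of the 12 higher calls held for MACS2 (splicing factors, epithelial-mesenchymal transition, and mitochondrial mRNAs, the last by construction). For MeTDiff that background allows no higher call, since 95.4% of it had a MeTDiff peak and even a list with a peak in every member would give p = 0.176 or more (Fisher's exact test).

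The actin cytoskeleton and motility list was the highest in the MeTDiff list. Of its 49 genes, 38 had a MeTDiff peak (77.6%, adjusted p = 6.5e-10, Fisher's exact test) and 27 a MACS2 summit (55.1%, adjusted p = 4.9e-09, Fisher's exact test). Filamin A (FLNA) had 10 MeTDiff peaks, the strongest of 26.4-fold, and 10 summits, with a highest score of 85.6. Cofilin (CFL1) had a highest score of 80.9, beta-actin (ACTB) 78.5 and non-muscle myosin heavy chain (MYH9) 59.5. Moesin (MSN) had a largest fold of 6.88 and talin (TLN1) of 16.4. Of 22 intermediate filament genes, the family of NES, 10 had a MeTDiff peak (adjusted p = 0.191, Fisher's exact test) and 7 a summit (adjusted p = 0.0961, Fisher's exact test), and neither share passed the test. With the top-ranking peaks both passed (odds ratio 1.85 before and 2.96 after for MeTDiff, adjusted p = 0.0386, and 2.53 before and 3.77 after for MACS2, adjusted p = 0.023, Fisher's exact test). The keratin KRT8 had a highest score of 52.1, vimentin (VIM) of 43.4 and lamin A/C (LMNA) of 42.4.

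Signalling and cancer genes were also overrepresented. Among 50 genes of RAS, MAPK and PI3K signalling 35 had a MeTDiff peak (70%, adjusted p = 3.0e-07, Fisher's exact test) and 16 a summit (32.0%, adjusted p = 0.00669, Fisher's exact test). The kinase gene AKT2 had 16 MeTDiff peaks, the strongest of 36.0-fold, and 14 summits, and the adaptor gene GRB2 reached 23.4-fold. ERBB2, a receptor tyrosine kinase gene, had 3 summits, of which 2 lay inside MeTDiff peaks that were not assigned to it. Of 32 driver genes of pancreatic cancer, 18 had a MeTDiff peak (56.2%, adjusted p = 0.00702, Fisher's exact test) and 11 a summit (34.4%, adjusted p = 0.0227, Fisher's exact test). MYC had 8.82-fold enrichment, ARID1B 18.5-fold and BRCA1 23.0-fold, and STK11 had 8 MeTDiff peaks. Without genes whose span overlaps another gene, the call of the driver list ended for both peak lists (adjusted p = 0.441 for MeTDiff and 1 for MACS2, Fisher's exact test), with 6 of its 32 genes left and odds ratios from 2.86 to 2.02 for MeTDiff and from 2.85 to 0.966 for MACS2. The MACS2 call of the signalling list, with an odds ratio of 2.56, ended there too (odds ratio 1.21, 15 of 50 genes left, adjusted p = 0.837, Fisher's exact test) and with the top-ranking peaks (odds ratio 2.21, adjusted p = 0.0743, Fisher's exact test).

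Cell cycle and mitosis genes had a MeTDiff peak in 32 of 59 cases (adjusted p = 0.000777, Fisher's exact test) and a summit in 16 (adjusted p = 0.0356, Fisher's exact test). The proliferation marker MKI67 had 10.8-fold enrichment and the replication helicase gene MCM2 16.3-fold. Of 33 genes of apoptosis and the p53 response, 16 had a MeTDiff peak (adjusted p = 0.0454, Fisher's exact test) and 8 a summit (adjusted p = 0.256, Fisher's exact test). BBC3, which encodes the pro-apoptotic protein PUMA, had 14.8-fold enrichment. The MeTDiff call of this list, with an odds ratio of 2.09, ended under all 4 alternatives besides the either-list background, with odds ratios from 0.949 to 2.02. The MACS2 call of the cell cycle list, with an odds ratio of 2.02, ended with the top-ranking peaks (odds ratio 1.81, adjusted p = 0.152, Fisher's exact test), within strata of gene span (odds ratio 1.81, adjusted p = 0.069, Mantel-Haenszel chi-square test) and without overlapping genes (odds ratio 1.61, 32 of 59 genes left, adjusted p = 0.36, Fisher's exact test).

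Genes of epithelial-mesenchymal transition and invasion passed the test in the MACS2 list, with 17 of 52 (32.7%, adjusted p = 0.00431, Fisher's exact test). In the MeTDiff list 18 had a peak (34.6%, adjusted p = 0.553, Fisher's exact test), and the difference between the peak lists was not tested. LAMC1, a laminin chain gene, had 20.3-fold enrichment and a highest score of 71.8, LAMA5 had 12 MeTDiff peaks and 19 summits, and the gelatinase gene MMP2 had 8.64-fold enrichment. The integrin gene ITGB5 had a highest score of 55.9.

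Protein synthesis and folding genes formed another such group. Of 79 cytosolic ribosomal protein genes 48 had a MeTDiff peak (60.8%, adjusted p = 4.8e-07, Fisher's exact test) and 31 a summit (39.2%, adjusted p = 2.5e-06, Fisher's exact test). RPS9 had 15.2-fold enrichment, RPL30 17.7-fold and RPL8 a highest score of 50.4. Of 48 translation factor genes 29 had a MeTDiff peak (60.4%, adjusted p = 8.9e-05, Fisher's exact test) and 21 a summit (43.8%, adjusted p = 1.9e-05, Fisher's exact test). EIF3B, a subunit of an initiation complex, had a score of 100, and PABPC4, a poly(A)-binding protein gene, 45.7-fold enrichment. Aminoacyl-tRNA synthetase genes, whose products charge tRNAs, had a MeTDiff peak in 25 of 38 cases (65.8%, adjusted p = 4.3e-05, Fisher's exact test) and a summit in 11 (28.9%, adjusted p = 0.0675, Fisher's exact test). The MACS2 share passed with the top-ranking peaks (odds ratio 2.21 before and 3.60 after, adjusted p = 0.00396, Fisher's exact test). NARS1 stood out among them with 37.0-fold enrichment and a score of 91.9.

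Of 39 genes of the integrated stress and unfolded protein responses, 27 had a MeTDiff peak (69.2%, adjusted p = 9.4e-06, Fisher's exact test) and 16 a summit (41.0%, adjusted p = 0.000478, Fisher's exact test). HSPA5, the chaperone of the endoplasmic reticulum, had 7.17-fold enrichment and the amino acid transporter gene SLC7A5 a highest score of 77.6. Of 20 heat shock and chaperone genes, 15 had a MeTDiff peak (adjusted p = 0.00018, Fisher's exact test) and 10 a summit (adjusted p = 0.00116, Fisher's exact test), with 31.1-fold enrichment in HSPH1. The MACS2 call of the chaperone list ended without overlapping genes (odds ratio 5.43 before and 3.46 after, 12 of 20 genes left, adjusted p = 0.081, Fisher's exact test).

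Enzymes that modify tRNA, the group of TRMT5, were moderately overrepresented. Of 66 genes 30 had a MeTDiff peak (45.5%, adjusted p = 0.0223, Fisher's exact test) and 15 a summit (22.7%, adjusted p = 0.149, Fisher's exact test). The MeTDiff call ended with only the top-ranking peaks (odds ratio 1.85 before and 1.60 after, adjusted p = 0.17, Fisher's exact test), while the MACS2 share passed without overlapping genes (odds ratio 1.60 before and 2.81 after, 30 of 66 genes left, adjusted p = 0.0283, Fisher's exact test). The pseudouridine synthase gene PUS1 had 10.5-fold enrichment, TRMT44 7.50-fold, TRMT1 7.88-fold and OSGEP 14.4-fold. Of 29 genes of mRNA methylation 16 had a MeTDiff peak (adjusted p = 0.0147, Fisher's exact test) and 8 a summit (adjusted p = 0.148, Fisher's exact test). Among them were the m6A methyltransferase gene METTL3, with 13.4-fold enrichment, and the cap methyltransferase gene CMTR1, with 24.4-fold. Without overlapping genes 15 of the 29 were left and the MeTDiff share missed the threshold (adjusted p = 0.0792, Fisher's exact test), while its odds ratio did not fall (2.73 before and 3.04 after). Splicing factor genes had a MeTDiff peak in 27 of 42 cases (64.3%, adjusted p = 4.3e-05, Fisher's exact test) and a summit in 24 (57.1%, adjusted p = 9.1e-09, Fisher's exact test). SRSF9 had 54.2-fold enrichment and SNRNP70, a protein gene of the U1 particle, a score of 63.0.

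In energy metabolism, 16 of 24 glycolysis genes had a MeTDiff peak (66.7%, adjusted p = 0.00106, Fisher's exact test) and 12 a summit (50.0%, adjusted p = 0.000411, Fisher's exact test). PKM had a score of 99.3, TPI1 of 70.3, and the lactate transporter gene SLC16A3 had 14 MeTDiff peaks. Of 75 nuclear genes of oxidative phosphorylation 33 had a MeTDiff peak (44.0%, adjusted p = 0.0235, Fisher's exact test) and 17 a summit (22.7%, adjusted p = 0.144, Fisher's exact test), with 26.2-fold enrichment in UQCR11, in a peak that overlapped one of another gene ID. Without overlapping genes 50 of the 75 were left and that MeTDiff share missed the threshold (adjusted p = 0.0578, Fisher's exact test), while its odds ratio did not fall (1.75 before and 1.87 after).

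The 13 mRNAs of the mitochondrial genome had a lower share in the MeTDiff list and a higher share in the MACS2 list than other genes. A test between the peak lists was run for this list alone, after the split had been seen, and is not used here. None had a MeTDiff peak (0 of 13, adjusted p = 0.0197, Fisher's exact test), whereas 7 had a summit (53.8%, adjusted p = 0.00424, Fisher's exact test). MT-CO2 had a score of 36.5, MT-CO1 of 34.8 and MT-CO3 of 23.1. The MACS2 call ended with only the top-ranking peaks (odds ratio 6.34 before and 3.01 after, adjusted p = 0.152, Fisher's exact test). The MeTDiff call ended there as well (0 of 13, adjusted p = 0.193, Fisher's exact test), without overlapping genes (0 of 8, adjusted p = 0.0885, Fisher's exact test) and within strata of gene span (adjusted p = 0.184, Mantel-Haenszel chi-square test).

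Underrepresented were the histone genes of the replication clusters. The RNA was polyA+ selected, and how much of these mRNAs the selection kept is unknown here. A low share therefore does not show less m1G on them. Of 56 genes 3 had a MeTDiff peak (5.36%, adjusted p = 1.8e-05, Fisher's exact test) and 1 a summit (1.79%, adjusted p = 0.00417, Fisher's exact test). H4C5 had 2.38-fold enrichment and H2AC8 1.70-fold. Within strata of gene span the calls ended (adjusted p = 0.0615 for MeTDiff and 0.0709 for MACS2, Mantel-Haenszel chi-square test), with odds ratios from 0.125 to 0.332 for MeTDiff and from 0.0983 to 0.169 for MACS2. The MACS2 call also ended with the top-ranking peaks (odds ratio 0.182, adjusted p = 0.0953, Fisher's exact test).

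Markers of other cell types of the pancreas were rare. Without expression values, a low share cannot tell an absent transcript from one without m1G. Of 20 acinar genes 1, CEL, had a MeTDiff peak (adjusted p = 0.0197, Fisher's exact test), and of 20 endocrine genes 1, MAFA (adjusted p = 0.0197, Fisher's exact test). In the MACS2 list there were 0 acinar genes (adjusted p = 0.0904, Fisher's exact test) and 1 endocrine gene (adjusted p = 0.381, Fisher's exact test). Immune and stromal markers had a MeTDiff peak in 3 of 26 cases (adjusted p = 0.0416, Fisher's exact test), COL3A1, COL1A1 and CD68, and a summit in 2 (adjusted p = 0.433, Fisher's exact test). Ductal epithelium genes, the lineage of this tumour, had a MeTDiff peak in 8 of 20 cases (adjusted p = 0.489, Fisher's exact test) and a summit in 3 (adjusted p = 1, Fisher's exact test). Among them were KRT8, KRT19 and SOX9. Of 25 abundant noncoding RNAs 10 had a MeTDiff peak (adjusted p = 0.422, Fisher's exact test) and 8 a summit (adjusted p = 0.073, Fisher's exact test). The MACS2 share, with an odds ratio of 2.55, passed with the top-ranking peaks (odds ratio 3.91, adjusted p = 0.012, Fisher's exact test), within strata of gene span (3.07, adjusted p = 0.00926, Mantel-Haenszel chi-square test), with any gene touched by a summit (3.56, adjusted p = 0.00562, Fisher's exact test) and without overlapping genes (7.77, adjusted p = 0.002, Fisher's exact test), but not with the either-list background (2.19, adjusted p = 0.601, Fisher's exact test). The MeTDiff share passed only with any gene touched by a peak (odds ratio 1.48 before and 2.44 after, adjusted p = 0.0444, Fisher's exact test). The nuclear RNA NEAT1 had 10 MeTDiff peaks, and RPPH1, the RNA of ribonuclease P, a score of 43.1. The lower share of acinar, endocrine and immune or stromal markers lost its call with the top-ranking peaks (adjusted p = 0.193, 0.193 and 0.25, Fisher's exact test) and without overlapping genes (adjusted p = 0.103, 0.16 and 0.0521, Fisher's exact test), where the odds ratios were still 0.356 or less. The call of immune and stromal markers also ended within strata of gene span (odds ratio 0.322, adjusted p = 0.0615, Mantel-Haenszel chi-square test).

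**Figure D2:**
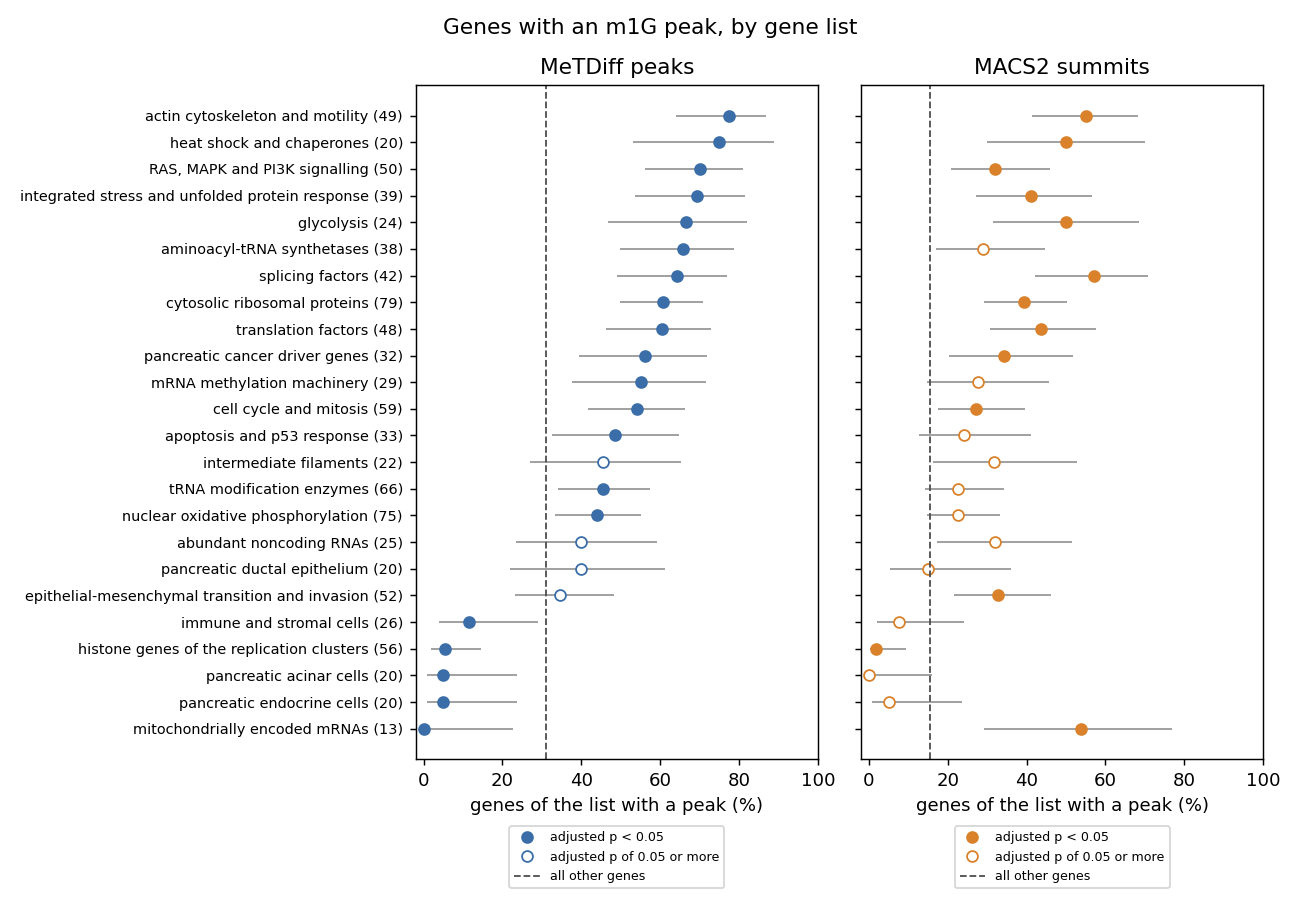
Share of the genes of each list with a MeTDiff peak (left) or a MACS2 summit (right), in percent, with the number of genes in brackets. Bars are 95% Wilson intervals, filled points passed the test, and the dashed line is the share of all other genes. The highest share in the left panel is that of actin cytoskeleton genes, 77.6%, and in the right panel that of splicing factors, 57.1%, and mitochondrially encoded mRNAs have 0% in the left panel and 53.8% in the right.

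Most genes with a MACS2 summit also had a MeTDiff peak, but fewer of the positions coincided. Both lists were called on the same series of libraries, so an overlap above random was bound to arise. It compares the 2 callers and is not independent evidence for the sites. Of the 3117 background genes with a MACS2 summit, 2814 (90.3%) also had a MeTDiff peak, where independent lists would share 969 (odds ratio 36.8). They made up 45.2% of the 6220 background genes with a MeTDiff peak. By position, 1910 of the 5206 summits in 1 gene span fell inside a MeTDiff peak, 36.7% against 5.35% for random positions in the same genes (p = 0.001, one-sided permutation test, the smallest it can give). Gene spans include introns, which lowers the random share, and in genes with a span under 5000 bp it was 40.1% against 15.6% (p = 0.001, one-sided permutation test). Over all 6264 summits it was 35.3% (interval 34.1 to 36.5), and for the 410 summits in no gene span 6.34% (interval 4.36 to 9.13). The share rose from 27.5% in the 20% of summits with the lowest scores to 43.8% in the 20% with the highest (p = 1.4e-17, Fisher's exact test). In reverse, 12.4% of MeTDiff peaks (interval 11.9 to 12.8) contained a summit, from 2.17% in the 20% with the lowest folds to 30.7% in the 20% with the highest (p = 2.0e-278, Fisher's exact test). The overlap depended on how a summit was extended, and with 150 bp on either side 82.1% of the summits met a MeTDiff peak, against 14.2% over 20 random placements. With at least 50% of the shorter interval shared it was 62.5%, with whole peak spans 56.2%, and with reciprocal overlap of 50% it was 24.7%.

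Peaks gathered at the 5′ ends of genes. Within 500 bp of the 5′ end lay 2629 of the 15382 named MeTDiff peaks (17.1%), and within 500 bp of the 3′ end 1014 (6.59%). Counted by gene, 2175 genes had a peak at the 5′ end only, 655 at the 3′ end only and 303 at both. The 3′ end thus took 23.1% of the genes with a peak at a single end (interval 21.6 to 24.7, p = 5.4e-189, exact binomial test). Examples were MOGS, where the midpoint of the strongest peak was 196 bp from the 5′ end, RNASET2, at 129 bp, and MKI67, at 175 bp. At the other end, the strongest peak of MSN lay 199 bp from the 3′ end. MACS2 summits showed the same direction, with 1088 of 4738 near the 5′ end (23.0%) and 195 near the 3′ end (4.12%). Only the 4738 summits in genes with a named MeTDiff peak could be used, since strand came from that list. The 3′ end took 12.9% of the genes (interval 11.1 to 14.99, p = 7.8e-160, exact binomial test). Peaks near the 5′ end had a median fold of 5.53, against 3.80 near the 3′ end and 3.96 elsewhere.

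The size of this difference depended on the window and on the folds used. The 3′ share in the MeTDiff list was 14.9% with windows of 250 bp, and 36.3% without peaks whose fold was a multiple of 0.25 within rounding. In the MACS2 list it was 1.10% with 250 bp and 23.8% with 1000 bp.

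**Figure D3:**
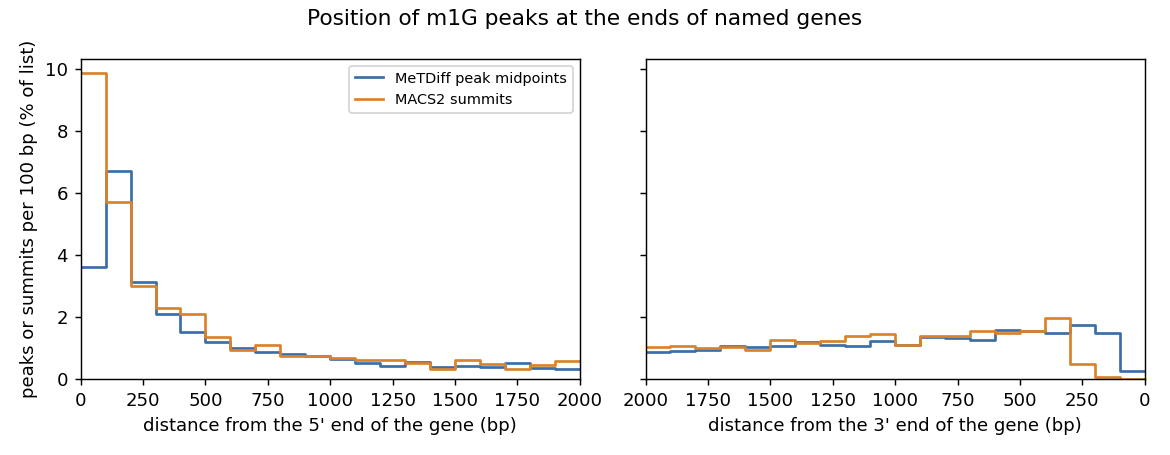
Position of MeTDiff peak midpoints and MACS2 summits at the 5′ end (left) and the 3′ end (right) of named genes, in bins of 100 bp, as a percentage of the peaks or summits of each list. Both lists are denser near the 5′ end, where MACS2 summits are highest in the outermost bin (9.86%) and MeTDiff midpoints in the next bin (6.72%, against 3.63% in the outermost), and MACS2 summits are nearly absent next to the 3′ end, with 27 within 300 bp.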

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

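Tests of the share of summits in genes with a MeTDiff peak and of the highest-scoring summits were chosen after the overlap had been seen. All moves of summits, counting any overlap of a window around them, the limit to folds under 10 and the removal of folds on steps of 0.25 were also chosen after seeing the data.

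Some MACS2 summits lay outside nuclear mRNA genes. There were 410 summits in no gene span, and 383 of them lay within 1000 bp of a gene, at a median distance of 35 bp. Another 14 summits lay in nuclear ribosomal RNA genes, and 19 on the mitochondrial chromosome, of which 5 were in ribosomal RNA genes and 13 in protein-coding genes, all members of the gene lists. The MeTDiff list had 1 peak on that chromosome, in MT-RNR2 with a fold of 3.10.

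Most MACS2 summits lay outside every MeTDiff peak, although 90.3% of the background genes with a summit had such a peak. Neither position outside annotated genes nor low scores account for all of it. Of the summits in genes with a MeTDiff peak 38.6% fell inside a peak, and of the highest-scoring 20% of summits 43.8% did. Both were under a mark of 80%, which was set after the overlap had been seen. The share was 27.5% in the lowest-scoring 20%, so low scores may still contribute. A candidate explanation is a fixed displacement along the transcript, as summits within 300 bp of the midpoint of an unspliced peak lay a median of 98 bp towards the 5′ end (interval 95 to 100), with the same direction on the plus strand (95 bp) and the minus strand (101 bp). On even chromosomes, moving summits towards the 3′ end by the 99 bp found on odd chromosomes raised the share inside a peak from 38.7% to 72.8%, and the opposite move lowered it to 15.3%. The mark set for this move was 50%, and 72.8% stays under the 80% used for the other causes. With 150 bp on either side 80.7% of all summits met a peak, which reaches the 80% used for the other causes. Imprecise summit position thus met that mark and stays a candidate. Imprecision without direction alone would not place 89.8% of the nearby summits on the 5′ side. No biological explanation was tested.

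More genes had a peak at the 5′ end than at the 3′ end. Few input reads at the 5′ end may contribute. Without folds on steps of 0.25 the 3′ share rose from 23.1% to 36.3%, still under 50%. Such steps stood in for small input counts, as no read counts were available. They miss some small counts, so the filter cannot tell whether few input reads are the whole cause. Folds of 10 or more have 1 decimal and meet such steps by rounding, but among folds under 10, read within 0.005, steps held 49.7% at the 5′ end and 26.8% at the 3′ end, and leaving them out moved the 3′ share from 28.1% to 37.8%. Weak calls are argued against by a 3′ share of 22.1% among the peaks with the smallest p. Peaks of the same ID often share a p, so this ranks single peaks only in part. In the MACS2 list the displacement was 98 bp, and its interval reaches the bound of 100 bp set beforehand. The 3′ share there was 18.2% once summits were moved back. GC content and binding of the antibody to other marks near the cap are open and untested. So is a preference of m1G itself for the 5′ parts of mRNAs. A comparison with TRMT5-depleted cells would show whether these peaks depend on TRMT5, which alone would not settle that preference.

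The same bases were reported as peaks on both strands. In 699 pairs, peaks of different IDs on opposite strands overlapped, and 2231 peaks (12.1%) overlapped a peak of another ID. Of the 137 opposite-strand pairs that shared at least 90% of their bases, 65.0% (interval 56.7 to 72.4) had folds within 10% of each other. The share was 57.5% for the 334 such pairs of different IDs on the same strand, and 8.24% for random pairs. Pairs on opposite strands thus matched no less often than pairs on the same strand, as they would if MeTDiff had counted reads without strand. In that case 1 enriched site may stand under 2 genes. No biological explanation was tested for it.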

How the results depend on the processing

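No paired analysis was possible because the peak lists carry no library columns, and for the same reason no replicate was left out. Alternatives fixed for differential peaks, base composition, transcript features and direction of change could not be computed from these lists. The overlap of the peak lists stayed above random placement in all 11 alternatives, from 15.3% to 82.1%, and the excess of 5′ ends stayed in all 13 of both lists together, with 3′ shares from 1.10% to 37.8%. Of the 18431 MeTDiff peaks 2277 held a MACS2 summit, a set that is smaller by construction, while an FDR under 0.01, a fold of at least 2 or leaving out peaks shared with another ID moved the number by less than 1.5 times.

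Of the 15 gene lists with a higher share in the MeTDiff list, 10 kept their call under all alternatives but the background of genes with a peak in either list. In the MACS2 list it was 7 of 12. Of the 5 lists with a lower share for MeTDiff and the 1 for MACS2, 0 did. That background is void as a test of a higher MeTDiff share, since 95.4% of it had a MeTDiff peak and 0 of the 24 lists could reach p under 0.05 with a peak in every member (Fisher's exact test). There 1 list passed for MeTDiff (mitochondrial mRNAs) and 3 for MACS2 (mitochondrial mRNAs, splicing factors, and epithelial-mesenchymal transition). The mitochondrial mRNAs entered it through their summits alone, so their result there was fixed by construction and says nothing. In 8 lists for MeTDiff and 2 for MACS2 every member left in that background had a peak, and no odds ratio could be given. Without genes that overlap another gene 12 lists passed for MeTDiff. Calls gained by lists without one are given with those lists above.

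Among lists with a call, odds ratios for MeTDiff turned below 1 with the either-list background for translation factors (0.705), ribosomal proteins (0.464), oxidative phosphorylation (0.803), glycolysis (0.779), actin cytoskeleton (0.925), RAS signalling (0.852), apoptosis (0.779), mRNA methylation (0.779) and splicing factors (0.436), and with the top-ranking peaks for apoptosis (0.949). Among lists with a call for MACS2 they did so for RAS signalling with the either-list background (0.832) and for driver genes without overlapping genes (0.966). Lists without a call also turned, and their values are not given here. The MeTDiff values in the either-list background say nothing about a higher share.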

Other observations

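Peak density varied between chromosomes. Chromosome 22 had 171 MeTDiff peaks per 100 protein-coding genes, chromosome 16 had 157, chromosome 19 had 139 and chromosome 17 had 137, against 46.4 on chromosome 13 and 47.8 on chromosome X. MACS2 summits ran from 14.2 per 100 genes on chromosome 13 to 53.2 on chromosome 16, the mitochondrial chromosome aside. The median span of protein-coding genes was 14335 bp on chromosome 19 and 45740 bp on chromosome 13, but 16190 bp on the sparsely covered chromosome X.

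The genes with most MeTDiff peaks were chosen after their values were seen. The heparan sulfate proteoglycan gene HSPG2 had 19 peaks, EPPK1, PKD1 and TNRC18 had 18 each, AKT2 had 16 and the plectin gene PLEC 15. EPPK1 had 0 MACS2 summits, while PLEC had 15 and TNRC18 had 12.

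On the mitochondrial chromosome the summits spread over 7 mRNA genes and both ribosomal RNAs. The highest score was 43.0 in MT-RNR2, at position 2702, followed by 38.0 in MT-RNR1, at 745. Among small nuclear-encoded RNAs, 0 of the summits lay in a tRNA gene of the gene table, 2 lay in 7SL RNA genes (RN7SL1 and RN7SL3) and 1 each in RMRP and RPPH1. There were also 8 summits in miRNA genes and 2 in snoRNA genes. TRMT5 acts on tRNAs, which polyA+ selection leaves out for the most part.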
